A study of Drosophila melanogaster with 2 samples.

How the data were processed

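The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for fd59A (forkhead domain 59A), a forkhead-box transcription factor of Drosophila melanogaster. Per the labels, a transgenic line carried fd59A fused to eGFP, a green fluorescent protein tag, and chromatin was precipitated with an antibody against GFP. Whole prepupae of both sexes were pooled, and the labels give their age as 24 day. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels. The 2 samples are biological replicates 2 and 3, which have separate biosample identities from 1 line, and they form 1 group. No control or input library is among the samples, so no comparison between conditions was made.

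The authors deposited a list of peaks and background regions for each replicate and a list called on the pooled alignments. A further list held pooled peaks thresholded by the irreproducible discovery rate (IDR), a measure of how well peaks repeat between replicates. Each list exists for builds dm6 and dm3 of the genome, per the file descriptions, and the calls used a control. The peak caller, its version, the IDR threshold and the scaling of the values are not given in the sources used here. The deposited signal value of each peak was taken as the authors' own score of peak height, and was used only to rank or describe peaks. The deposited −log10 q value of each peak was used for ties and for an alternative ranking. It sat at its maximum in 4305 of the 5327 dm6 IDR peaks, so that ranking by it with ties broken by signal gave the order by signal. Read totals are not in the lists, so sequencing depth is unknown. Intervals on shares of peaks cover counting error only, and peaks are not replicates.

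The dm6 lists were analysed with the dm6 sequence and Ensembl release 115 gene models. The dm3 lists were used only for counts, overlaps and chromosome arms, and no coordinate was converted between builds. Summits were placed in 7 classes in a fixed order: promoter (within 500 bp of the start site of any transcript, noncoding transcripts included), 5' UTR, 3' UTR, coding exon, intron, noncoding exon and intergenic. A summit was assigned to the protein-coding gene with the nearest transcription start site (TSS) if that was at most 10 kb away. Background regions were the 22917 pooled regions that overlap no IDR peak, and all ranked below the IDR peaks by pooled signal.

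Replicate overlap was tested with a 1-sided permutation test of 1000 placements of the replicate 3 peaks within the same chromosome arm, with both lists cut to the 5327 strongest peaks and summits matched within 100 bp. Gene classes were tested with a 2-sided permutation test of 1000 random placements of the summits within the same arm. Arms were tested with exact binomial tests against arm length. Each of 19 sequence motifs within 50 bp of the summit was compared with a point 250 bp to a randomly drawn side by an exact McNemar test. The 23 gene lists were compared with 100000 random lists matched on decile of TSS territory, the stretch of genome nearest to a gene's start sites, in a 2-sided permutation test. Random genes were drawn singly, so p may be too small for lists whose members are neighbours in the genome. The strongest and weakest 20% of peaks were compared with Fisher's exact test. All p-values were adjusted by the Benjamini-Hochberg method within each of these families, with calls at 0.05. Shares have Wilson 95% intervals. These tests, the lists and most alternatives were chosen before the data were examined.

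Genes were named by a fixed rule: fd59A, the genes of the 20 strongest IDR peaks, the 4 members of each called list with the strongest assigned peak, and every member of the forkhead and octopamine lists. Of 785 symbols fixed, 10 matched no gene name and were left out, mostly synonyms of members already listed, and 7 were matched through a current name. The forkhead list wrongly held Alh, which has no forkhead domain. The list was kept as fixed and also tested without Alh.

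The statistical code was tested on simulated data with 5327 peaks. Random gene lists of 20 genes gave p below 0.05 in 1.33% of 300 lists, and 76 of 100 lists of 20 genes with 10 planted hits were called. With 60% of summits planted as shared, 60.3% were matched. Alternatives varied the match distance, promoter width, peak number, background, gene assignment and genome build, and left out each replicate by taking the strongest peaks of the other alone. Added after the data were seen were draws from replicate 3's own list, dinucleotide shuffles of the summit windows, GC-matched placements, the list without Alh, matching on territory within 10 kb, and peaks strong in both replicates. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.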

Results

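Peaks of the anti-GFP precipitation of eGFP-tagged fd59A were mapped in whole Drosophila prepupae, in 2 biological replicates of 1 group. Because no control library is among the samples, signal not due to the tagged protein could not be told apart at any peak. The authors' IDR list held 5327 peaks in dm6, with a median width of 424 bp. It was made up of the 5327 regions of highest signal among the 29208 called on the pooled data. Not every one of them had a match in both replicates: 4938 (92.7%) had a summit within 100 bp in each list. Merging overlapping peaks gave 5022 regions covering 1.41% of the 7 main chromosome arms. Replicate 2 alone had 28127 listed regions. Replicate 3 had exactly 30000 in both dm6 and dm3, so its list appears to have been cut at that number. The dm3 version of the list held 5019 peaks. Signal spanned 28.3-fold from the weakest to the strongest IDR peak, with a median of 193 in the authors' units. Sequencing depth is unknown.

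Both replicates placed their strongest peaks at the same sites. Of the 5327 strongest peaks of replicate 2, 3996 (75.01%, Wilson 95% interval 73.8 to 76.2) had a replicate 3 peak of the same rank range within 100 bp, against a mean of 0.810% for random placement. Peaks drawn at random from replicate 3's own list gave a mean of 16.1% and at most 17.5% in 1000 draws. The 1-sided permutation p was 0.0010 against either, the smallest that 1000 draws can give. Among the 1000 strongest of each, 84.1% were shared. Over the whole lists 43.8% of replicate 2 regions were shared, a share that depends on where the replicate 3 list ends. Across the 4938 IDR peaks matched in both, the replicate signals had a Spearman rho of 0.81, described across peaks, which are not independent replicates. With −log10 q in place of signal, rho was 0.13, and 56.0% of these peaks in replicate 2 and 95.5% in replicate 3 were tied at the maximum.

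**Figure D1:**
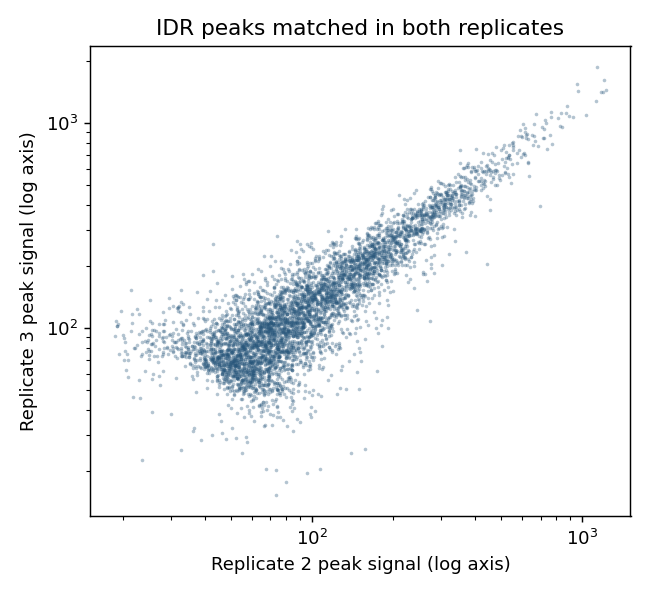
Signal of the 4938 IDR peaks matched in both replicates, replicate 2 on the horizontal and replicate 3 on the vertical axis, both logarithmic and in the authors' signal units; each point is a peak. The points rise together, with a Spearman rho of 0.81.

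The strongest peaks lay at promoters and in introns. The peak of highest signal (2996; 3L, 19590428 to 19590809) had its summit 94 bp from the TSS of CG14100. It was followed by a summit inside an intron of ush, which encodes a GATA cofactor, assigned to cbt, a zinc finger gene, 1402 bp away (signal 2841; 2L, 480885 to 481294). An intron summit in CG11050 came next (2671; 2L, 6612508 to 6612906). The fourth lay between genes on 2R at 13035097 to 13035543, with no protein-coding TSS within 10 kb. Ugalt, a UDP-galactose transporter gene, had a promoter summit 43 bp from its TSS (2579; X, 2703694 to 2704084). Other genes assigned to the 20 strongest peaks were HmgZ, a high mobility group gene, larp, an RNA-binding protein gene, Lk6, a kinase gene, Chro, a chromatin protein gene, and ph-p, a Polycomb group gene. The rest were CG4004, which had 2 of the peaks, CG9663, CG18549, PNPase, CG32772, Tcs5, eEF1gamma and CG4496. The 2 summits assigned to CG4004 lay in a noncoding exon of lncRNA:Vinr and in a promoter at lncRNA:CR44619. The second unassigned summit lay in an intron of osa on 3R, at 17704413. All 20 had a match in each replicate, and the lowest rank among them was 31 in replicate 2 and 24 in replicate 3.

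The fd59A gene (2R, 22868159 to 22870706, plus strand) had 1 assigned IDR peak. It ran from 22867416 to 22867839, with its summit 531 bp upstream of the TSS in intergenic sequence. Its signal of 113 ranked 4975 of 5327. The nearest replicate 2 peak ranked 6184 in that replicate, outside its 5327 strongest, and the replicate 3 peak ranked 4658.

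Promoters held 1733 of the 5327 IDR summits (32.5%, interval 31.3 to 33.8), which was 2.39 times the 13.6% ± 0.479 (SD over 1000 placements) of random placement. Introns held 46.1% against 39.6% ± 0.685 and were also higher. Coding exons were nearly empty, with 6 summits (0.113%, interval 0.0516 to 0.246) against 13.1% ± 0.460. The 3' UTRs held 0.544% against 5.04% ± 0.292, the 5' UTRs 0.451% against 0.781% ± 0.119 and intergenic sequence 19.5% against 27.3% ± 0.607, all lower. Adjusted permutation p was 0.0028 for each of these classes except the 5' UTR (0.012), and noncoding exons did not pass (0.24). The background regions had 18.5% of summits in promoters and 7.63% in coding exons. Against them the intron share no longer differed (45.2%, adjusted p = 0.30 by Fisher's exact test), and the 5' UTR call was lost without replicate 3 (0.619%, adjusted permutation p = 0.21) and among the 1000 strongest peaks (0.52). Placements matched on GC content ended both calls, with 44.7% in introns and 0.575% in 5' UTRs (adjusted permutation p = 0.053 and 0.24).

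**Figure D2:**
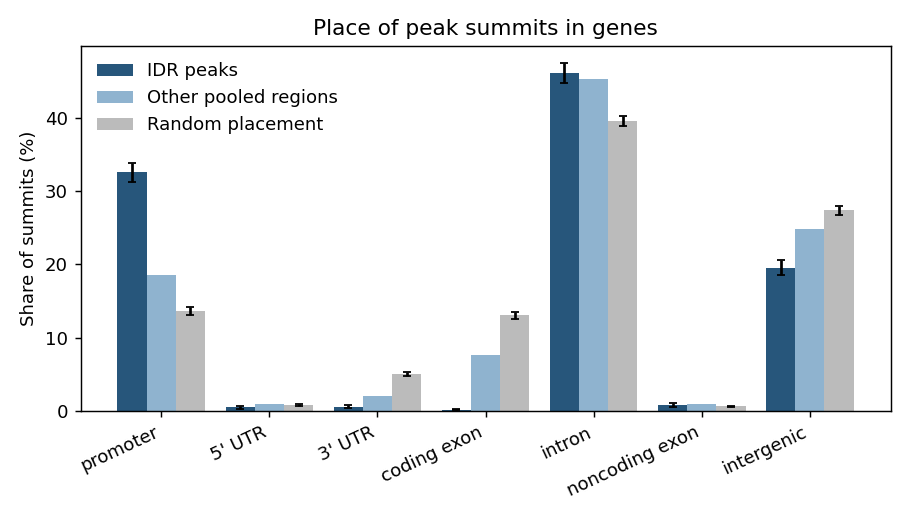
Share of summits (%) in each gene class for IDR peaks (Wilson 95% intervals), for the 22917 other pooled regions, and for random placement (mean and SD of 1000 placements). Promoters hold 32.5% of IDR summits and coding exons 0.113%.

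Promoter summits lay mostly upstream of the start site. Of the 1733, 79.1% (interval 77.1 to 81.0) were upstream of the nearest TSS, with a median of -133 bp and quartiles at -245 and -32 bp. The exact binomial p against an equal split was 6.7e-138 (2-sided), with peaks counted as independent. This test was not among those fixed beforehand, and the upstream share of random placements was not computed. The sequence under the summits was AT-rich. GC content within 50 bp of the summit averaged 33.4% ± 8.40 (SD over peaks), against 43.2% ± 10.1 in background regions and 42.3% ± 10.3 at random positions. In windows 300 bp to either side it reached 45.8% and 45.9%. Stronger peaks had lower GC content, from 30.8% in the strongest 20% to 35.7% in the weakest.

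**Figure D3:**
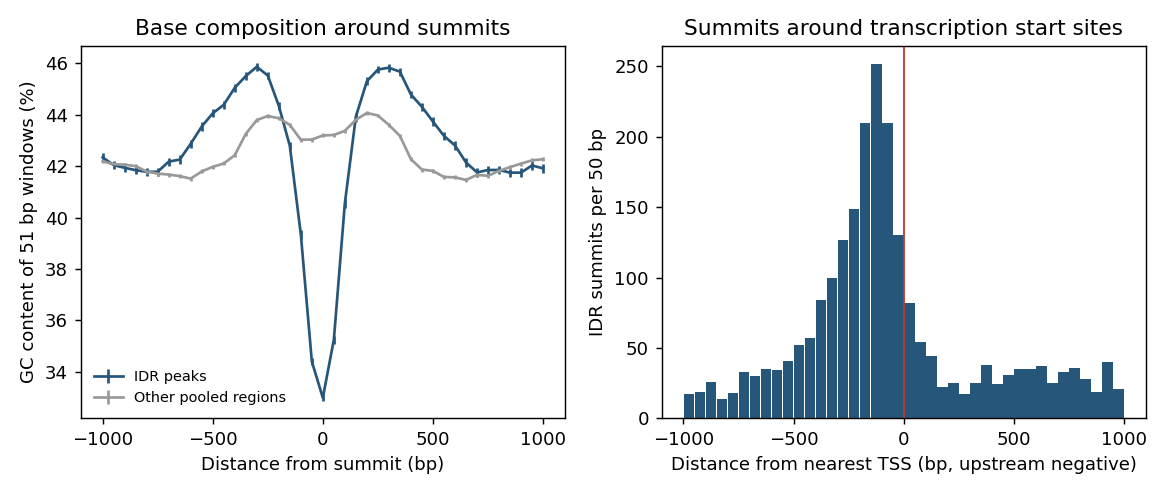
Left, mean GC content (%) of 51 bp windows by distance from the summit (bp) for IDR peaks and other pooled regions, with standard errors over peaks. Right, number of IDR summits per 50 bp by distance from the nearest TSS (bp, upstream negative); GC content dips at the summit and summits gather upstream, with a promoter median of -133 bp.

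The degenerate forkhead site RYMAAYA was found at 39.985% of summits (interval 38.7 to 41.3) and 31.2% of flanks, 1.28 times as often (exact McNemar adjusted p = 6.2e-21). Its scrambled control RMYAYAA rose more, from 23.2% in flanks to 35.1% at summits, 1.51 times (exact McNemar adjusted p = 2.9e-39). The forkhead core GTAAACA did not differ (2.22% and 2.27%, adjusted p = 0.89, exact McNemar). ATAAACA was at 4.66% of summits and 3.59% of flanks (adjusted p = 0.011, exact McNemar), a call lost without replicate 3 (adjusted p = 0.26). The other motifs found more often at summits were the AT-rich GATA site WGATAR (22.8% and 13.6%) and homeodomain site TAATTA (9.89% and 4.99%). Found less often were GACGC, the alternate forkhead site called FHL (4.22% and 10.5%, adjusted p = 5.3e-35, exact McNemar), the GAGA factor site GAGAG (10.2% and 17.8%), CACACA (6.25% and 12.3%), the E-box sites CAGCTG (2.38% and 5.12%) and CACGTG (0.582% and 1.28%), the AP-1 site and the Grainyhead site. The Grainyhead call was lost without replicate 3 (adjusted p = 0.77, exact McNemar) and among the 1000 strongest peaks (0.053). The AP-1 call was lost among the 2663 strongest peaks (adjusted p = 0.23, exact McNemar), the 1000 strongest (0.64), against background regions (0.087) and against shuffles (0.28), and the CACGTG call against shuffles (0.081). The DREF site TATCGATA (0.507% and 0.357%), the M1BP site GGTCACACT (0.263% and 0.188%), the Sox site ACAAAG (6.83% and 7.68%), CAGGTA, AGGTCA and TGATTAAT did not pass. The DREF site passed as higher with windows of 100 bp either side (adjusted p = 0.026, exact McNemar) and without replicate 3 (0.023), and Sox as lower among the 1000 strongest (0.038). Against shuffles, DREF (3.17 times) and M1BP (11.1 times) passed as higher. Sox (0.838 times), CAGGTA (0.810), AGGTCA (0.727) and TGATTAAT (0.386) passed as lower, each of these motifs with an adjusted permutation p of 0.029. Flanks were richer in GC than summits, and against dinucleotide shuffles of the summit windows the direction turned for 7 of these called motifs: ATAAACA, GAGAG, CACACA, CAGCTG, WGATAR, TAATTA and the Grainyhead site. Of these, ATAAACA and the Grainyhead site did not differ detectably from their shuffles.

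Peak class changed with strength. Promoters held 39.7% of the summits in the strongest 20% (1065 peaks, interval 36.8 to 42.7) and 29.8% in the weakest (27.1 to 32.6), with an adjusted p of 5.2e-06 by Fisher's exact test. RYMAAYA was at 44.5% and 38.9% (adjusted p = 0.0095), and GAGAG at 7.51% and 12.5% (adjusted p = 0.00024), both by Fisher's exact test. Between the strongest and weakest 10% the RYMAAYA difference did not pass (adjusted p = 0.093, Fisher's exact test). GC content was also lower in the strongest 20% (30.8%) than in the weakest (35.7%), and these tests did not match it. Dinucleotide shuffles of the summit windows held RYMAAYA at 37.1% for all peaks and 41.0% for the 1000 strongest. The observed share was 1.08 times the shuffled mean in each set.

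The X chromosome held 997 peaks, or 18.7% (interval 17.7 to 19.8) against 17.1% of arm length (exact binomial adjusted p = 0.0037). Arms 3L (22.8% against 20.4%, adjusted p = 6.3e-05) and 2L (18.4% against 17.1%, adjusted p = 0.014) were also higher by the exact binomial test. Arm 3R was lower (21.9% against 23.3%, adjusted p = 0.014, exact binomial), a call lost without replicate 2 or 3 (adjusted p = 0.094 and 0.056) and held against background regions (24.8%, adjusted p = 3.1e-05, Fisher's exact test). 2R did not differ (18.1% against 18.4%, adjusted p = 0.60, exact binomial), but was lower among the 2663 strongest peaks (16.6%, adjusted p = 0.018) and the 1000 strongest (15.2%, adjusted p = 0.021). Among the 1000 strongest peaks the X (adjusted p = 0.075), 2L (0.075), 3L (0.060) and 3R (0.79) calls were lost by the exact binomial test, and 3R also among the 2663 strongest (0.30). The fourth chromosome held 5 peaks (0.0939% against 0.980%) and Y none, and both were lower. Background regions were also few on the fourth chromosome (0.161%) and none lay on Y, and against them neither differed (adjusted p = 0.53 and 1 by Fisher's exact test). Against them the 3L call was also lost (22.2% of background, adjusted p = 0.53), and 2L lay below background (19.2%, adjusted p = 0.45, Fisher's exact test). The X share stayed higher than that of background (15.7%, adjusted p = 6.4e-07, Fisher's exact test).

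Of 13968 protein-coding genes, 2648 (19.0%) had an assigned IDR summit, and 4464 of the summits were assigned. Of the 23 lists, 5 had more genes with a summit than matched random lists and 2 had fewer. Cytosolic ribosomal protein genes had a summit in 48 of 93 members against 12.8 ± 3.18 (SD over random lists) for random lists, 3.75 times as many (adjusted permutation p = 0.00023). Of their 52 summits, 47 lay in promoters and 0 in coding exons or 3' UTRs. The strongest were at RpS27 (signal 561), RpL37A (385, 9636 bp from the TSS in an intron of another gene), RpL34b (371) and RpL32 (368). Only 1 ribosomal protein gene was among those of the 1000 strongest peaks, 0.319 times the number in random lists there (adjusted permutation p = 0.86). Proteasome genes, another housekeeping group, had a summit in 5 of 48 (6.38 expected, adjusted permutation p = 0.90).

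Wnt, Hedgehog and Dpp pathway genes had a summit in 20 of 30 members against 9.27 ± 2.46 (adjusted permutation p = 0.00092). The strongest were at dpp, a BMP-type ligand gene (signal 1491, intron), fz, a Wnt receptor gene (974), Wnt10 (788) and brk, a repressor of Dpp targets (768). These summits lay 1741 to 5271 bp from the TSS. With summits limited to 1000 bp of a TSS, the list had 0.914 times the random number. Genes that respond to the steroid hormone ecdysone had a summit in 16 of 23 against 7.81 ± 2.21 (adjusted permutation p = 0.0039). ImpL2, an insulin-binding protein gene (signal 1472), the nuclear receptor gene Hr4 (1036), Eip93F (967) and the ETS factor gene Eip74EF (895) had the strongest. By share of summits against background regions, the ecdysone list did not pass (1.23 times, adjusted p = 0.33, Fisher's exact test), nor did it among the 1000 strongest peaks (2.89 times, adjusted permutation p = 0.081).

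Forkhead genes had a summit in 12 of 18 listed members against 5.21 ± 1.89 (adjusted permutation p = 0.0081). They were CHES-1-like (10 peaks, strongest signal 974), jumu (816), Alh (664), foxo (593), FoxK, slp2, fkh, bin, croc, fd96Cb, FoxL1 and fd59A. FoxP, fd102C, fd19B, fd3F, fd96Ca and slp1 had none. Alh has no forkhead domain, and the list without it was 2.26 times the random number (adjusted permutation p = 0.018). The call, at 2.30 times the random number, was lost with summits within 1000 bp of a TSS (1.92 times, adjusted permutation p = 0.32) and within the gene or 1000 bp of it (1.44 times, 0.57). It was also lost among the 2663 strongest peaks (1.86 times, adjusted permutation p = 0.40) and the 1000 strongest (2.62 times, 0.45). Heat shock genes had a summit in 7 of 16 against 2.48 ± 1.40 (adjusted permutation p = 0.031), led by Hsp27 (signal 1483), Hsp83 (447), Hsp26 (302) and CG4456 (195). Hsp27, Hsp26 and CG4456 are neighbours on 3L, which the random lists did not match, so this p may be too small. That call was lost without replicate 3 (2.13 times, adjusted permutation p = 0.27), among the 2663 strongest peaks (3.40 times, 0.091) and the 1000 strongest (2.94 times, 0.86).

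Odorant and gustatory receptor genes had a summit in 8 of 179 against 34.5 ± 5.05 (adjusted permutation p = 0.00023). The strongest were at the neighbouring Gr93b (signal 806), Gr93d (705) and Gr93a (282), and at Gr89a (147). That call was lost among the 1000 strongest peaks (0.215 times, adjusted permutation p = 0.058). Cuticle genes had a summit in 8 of 122 against 18.2 ± 3.82 (adjusted permutation p = 0.022), led by Cpr72Ea (843), Cpr72Eb (479), Cpr51A (415) and Cpr62Ba (225), and that call was lost without replicate 3 (0.524 times, adjusted permutation p = 0.089), among the 2663 strongest peaks (0.485 times, 0.26) and the 1000 strongest (0.666 times, 1). None of the 12 octopamine and tyramine genes had a summit against 3.83 ± 1.58 (adjusted permutation p = 0.052): Oamb, Oct-TyrR, Octalpha2R, Octbeta1R, Octbeta2R, Octbeta3R, Tbh, Tdc1, Tdc2, TyrR, TyrRII and Vmat. That list passed as lower by share of summits against background regions (adjusted p = 0.012, Fisher's exact test) and with lists matched on territory within 10 kb (adjusted permutation p = 0.041). Marker lists for neurons (2 of 17), glia (6 of 12), muscle (6 of 20), fat body (3 of 16), hemocytes (3 of 14), trachea and epidermis (8 of 17), gut (0 of 17), salivary glue (0 of 10) and germline (4 of 19) did not pass. Neither did Hox genes (2 of 8), proneural and neuroblast factors (9 of 18), temporal neuroblast factors (9 of 20), neuronal identity factors (5 of 23) or the Notch pathway (10 of 23, adjusted permutation p = 0.13). The Notch list passed as higher with summits within the gene or 1000 bp of it (adjusted permutation p = 0.029), by Fisher's exact test on unmatched genes (adjusted p = 0.017) and by Fisher's exact test against background regions (0.017). By that test against background, Hox genes (0.269 times), neuronal identity factors (0.396), neuron markers (0.176) and gut markers (0) passed as lower, with adjusted p of 0.035, 0.019, 0.012 and 0.010. The test against background counts summits, not genes, and 1 gene can hold several. The 8 Hox genes, for example, had 48 background summits. Summits of 1 gene were counted as independent, so p may be too small for every list compared this way. Neuron markers also passed as lower among peaks strong in both replicates (adjusted permutation p = 0.037). By Fisher's exact test on unmatched genes, proneural and neuroblast (adjusted p = 0.0095), temporal neuroblast (0.018), glia (0.031) and trachea and epidermis lists (0.018) passed as higher. That test does not allow for TSS territory, and genes with long territories can collect more summits.

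**Figure D4:**
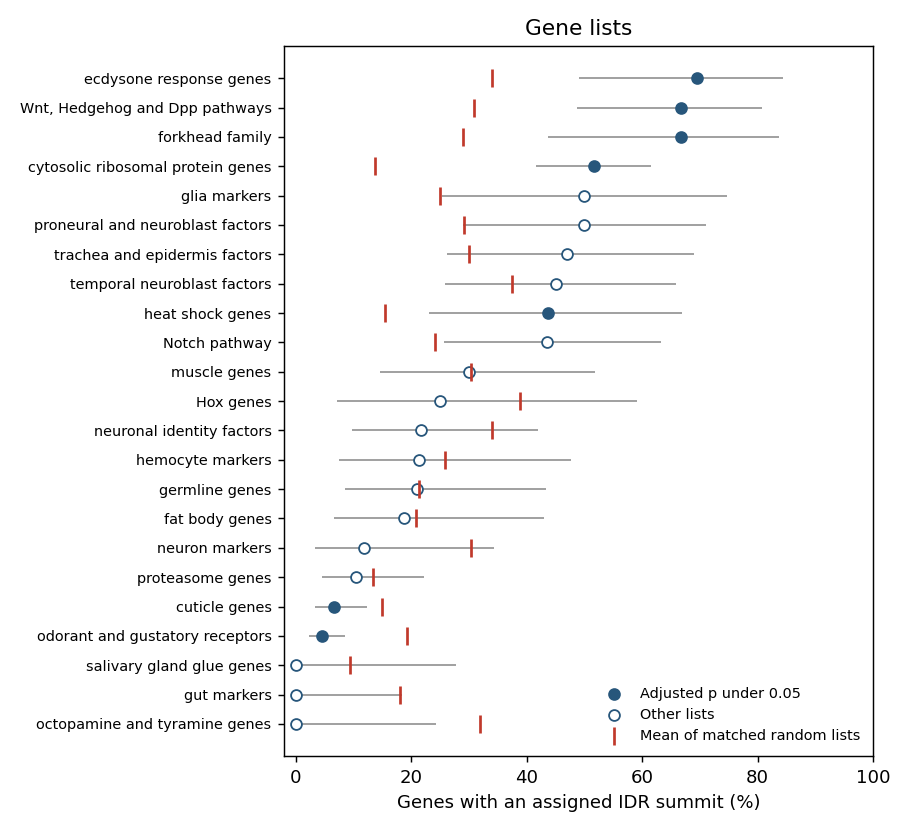
Share of each list's genes with an assigned IDR summit (%), with Wilson 95% intervals; filled points passed an adjusted p of 0.05, and red marks give the mean of matched random lists. Ribosomal protein genes (51.6%) lie above and receptor genes (4.47%) below their random lists.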

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

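In the dm3 lists, which the comparisons by gene class do not use, some regions lay on heterochromatic or unplaced sequences outside the main arms. There were 36 in the pooled list, 29 in replicate 2 and 85 in replicate 3, and 0 in the dm3 IDR list.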

How the results depend on the processing

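Alternatives on replicate 3's own list, shuffled sequences, GC-matched placements, 10 kb territory, peaks strong in both replicates and the list without Alh were chosen after the data were seen. IDR peak number, replicate overlap, and the promoter and coding-exon calls kept direction and call under every alternative run. The rank correlation between replicate signals fell to 0.13 with −log10 q, where 56.0% of values in replicate 2 and 95.5% in replicate 3 are tied at the maximum. Among the 1000 strongest peaks the X share was 19.4% and did not pass. Against background regions the fourth chromosome (0.0939%; 0.0797% in dm3) did not pass, and 2L (18.4%; 18.5% in dm3) lay below background. The Grainyhead site (1.15%) lay above background. Against dinucleotide shuffles the direction turned for ATAAACA (4.66%), GAGAG (10.2%), CACACA (6.25%), CAGGTA (1.97%), CAGCTG (2.38%), AGGTCA (1.88%), WGATAR (22.8%), AACNGGTT (1.15%), TAATTA (9.89%) and TGATTAAT (0.526%). Lists called higher numbered 5, but 3 with summits within 1000 bp of a TSS, 10 by Fisher's exact test on unmatched genes, 3 among the 2663 strongest peaks, 1 among the 1000 strongest, and 4 to 5 leaving out either replicate. Lists called lower numbered 2, but 7 against background regions, 1 among the 2663 strongest, 0 among the 1000 strongest, 1 to 2 leaving out either replicate, and 3 both with territory within 10 kb and among peaks strong in both replicates. The comparison of lists with background regions counted summits of the same gene as independent. With summits within 1000 bp of a TSS the Wnt, Hedgehog and Dpp list was at 0.914 times random, and among the 1000 strongest peaks the ribosomal protein list was at 0.319. The RYMAAYA difference between the strongest and weakest 10% was 5.26 percentage points and did not pass. The smaller sets also held fewer peaks, and the cause of these changes was not tested. No paired analysis was possible because there was 1 group. Depth is unknown, so its limit on weak peaks was not measured.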

Other observations

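Some genes collected many summits, chosen after their values were seen. The zinc finger gene shn had 19 assigned IDR peaks, tara and CG43658 14 each, Tlk 13, Mnt 12 and psq 11. Their TSS territories ran from 32848 bp (Mnt) to 101196 bp (CG43658). Of the strongest peaks of replicate 2, 485 (9.10%) had no summit within 100 bp anywhere in the replicate 3 list, and 101 overlapped no region there. For replicate 3 the counts were 526 (9.87%) and 126. The replicate 3 list appears to have been cut at 30000 regions, so the counts for replicate 2 depend on that limit. Promoters held 37.7% and 42.4% of these unmatched summits, against 31.2% and 33.5% of all strongest peaks of replicates 2 and 3. These differences were not tested.

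The tests on dinucleotide shuffles, GC-matched placements, gene bodies, proteasome genes and control libraries were chosen after the data were seen; no biological explanation was tested, since there was 1 group. RYMAAYA was more frequent at summits than in flanks, and base composition may account for part of this, since shuffled summit windows held it at 37.1% on average, against 31.2% in flanks. Flank windows were not shuffled, so an excess over shuffles need not be particular to summits. The observed 39.985% was above the highest of 100 shuffles (39.2%), so dinucleotide content alone did not give the whole summit share. The observed share was only 1.08 times the shuffled mean. The ratio was 1.10 in replicate 2 alone and 1.07 in replicate 3 alone, each above all 20 shuffles; it was 1.08 among the 1000 strongest peaks, where the 44.4% was below the highest of 20 shuffles (44.6%). Against their shuffles GTAAACA (2.22% and 2.15%) and ATAAACA (4.66% and 4.72%) did not differ detectably, and the forkhead site GACGC was lower (4.22% and 5.30%). The scrambled control equalled its shuffles (35.07% and 34.97%).

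Few summits lay in coding exons. AT-rich summits avoiding GC-rich exons could give part of this, since GC-matched placements had 3.90% of summits there on average, against 13.1% without matching. The lowest of 1000 GC-matched placements was 3.23%, above the observed 0.113%, which argues against GC content as the whole cause. The effect of the authors' calling stays open.

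Ribosomal protein genes carried peaks. Proteasome genes had a lower share with a peak (Fisher's exact p = 1.0e-06), so not every housekeeping group carried peaks as often. This comparison, chosen after the counts were seen, cannot speak for housekeeping promoters in general. Signal spread along transcribed bodies stays open, since 20 of the 52 summits (38.5%, interval 26.5 to 52.0) lay inside the assigned gene, an interval that includes 50%, although the median summit was at -25.5 bp from the nearest TSS. Signal not due to the tagged protein may be the source and cannot be told apart here, because 0 control immunoprecipitation libraries are among the samples.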
